A study of Mus musculus with 8 samples.

How the data were processed

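Whole cerebella of individual mouse pups were collected at postnatal day 2, and polyA RNA libraries were prepared from TRIzol-extracted RNA with an Illumina TruSeq kit, per the labels' protocols. There were 8 libraries, 4 from pups carrying Math1-Cre with one floxed and one null Sufu allele and 4 from control littermates. Math1-Cre is active in the cells that give rise to cerebellar granule neurons, so the recombined cells were one part of the tissue sampled. The series text gives the controls as carrying one floxed and one wild-type Sufu allele and the sample labels say only control, so whether the controls carried Cre is not given in the sources used here. The sample titles also carry a letter, P or R, each shared by 2 control and 2 mutant libraries. What the letter stands for is not stated, and it was used only as an alternative grouping.

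Each library came with 2 deposited tables. One held counts per gene for 24062 genes and the other held counts per exon bin for 219958 bins, both as whole numbers, and the authors had not normalized either. TopHat, HTSeq, DESeq2 and the mouse build mm9 are named in the submitters' processing notes, without versions, and the annotation is not given in the sources used here. The reference annotation at hand was of another build and was not used, so positions are given only as the chromosome and the order of bins in the bin names. The 5 summary lines of each gene table and the 4 of each bin table name no gene and were left out of library sizes and tests. In the gene tables those lines held 24.8 to 34.3% of all entries, of which reads outside annotated genes made up 12.2 to 17.7%, reads aligned to several places 11.7 to 16.0% and ambiguous reads 0.69 to 0.89%. Whether the counting used strand is not stated, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain. A total of 452 bin groups joined several overlapping genes under 1 name.

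Counts in genes summed to between 21479565 and 26638284 per library. A read can be counted in more than one bin. The 4 libraries of a group are separate pups, per the labels. All pairs of libraries within a group differed by more than counting noise, with a chi-square per degree of freedom of 7.76 to 85.7, so none was counted as a copy of another.

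Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust shrinkage, after the filterByExpr filter and TMM scaling, which left 15789 genes and gave scaling factors of 0.986 to 1.01. The test was two-sided, with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are in CPM, the counts scaled by edgeR to a common library size on the TMM-scaled sizes. Standard errors of log2 fold changes were taken from the fold change and its F statistic. DESeq2 1.42.0 was run as an alternative. The 30 gene lists, 393 genes in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), over the 28 lists with at least 5 tested members. List scores are the mean log2 CPM of the members in a library, less the mean of the 4 controls. Exon bins were tested with edgeR's diffSpliceDGE and Simes' method per gene, over 152302 bins of 13351 genes. Principal components were taken from the 500 most variable genes.

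The designs, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took Sufu; the 10 genes that rose and the 10 that fell most among those past the threshold, with no overlap between groups and a mean of at least 1 CPM in the higher group; every Hedgehog target and Fgf8; up to 4 passing members of each other list, or the 2 with the smallest p where none passed; and, for exon bins, Sufu and the 5 genes with the smallest adjusted p. Its second part named no gene because none passed, and not every gene the rule took is printed. Genes outside the rule whose levels are given are said to have been chosen after their values were seen, as were Enpp2 and Prlr. Other list members are named only where they make up a count of calls.

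The steps were tested on simulated counts made from the real means and library sizes. In the gene test of mutant against control, with 200 changed genes and the fitted dispersion, 32% of 50 genes changed 1.5-fold, 84% of those changed 2-fold, 98% of those changed 4-fold and 100% of those changed 8-fold were called, over 15691 genes, and 1.88% of calls were false. In the exon test, 64% of 100 genes with a bin changed 2-fold and 100% of those changed 4-fold were called over 13259 genes, with 7.87% of calls false. The list test called the 1 list that was raised 1.5-fold. Every simulated gene was drawn independently of the others, with no difference between title letters and no library set apart. The simulation therefore cannot tell how the tests, above all the list test with its preset correlation, fare on libraries that hold such structure.

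The alternatives were other scalings, DESeq2, limma-voom, robust shrinkage off, no filter beyond 1 count per gene and a stricter filter (at least 1 CPM in 4 libraries), the title letter as a block or one letter at a time, Xist as a covariate, other list and exon tests, a stricter bin filter (20 counts in 4 libraries) and each library left out in turn. Covariates made from Hox genes and from choroid plexus genes, leaving out both mutant libraries with Y-linked counts, and Xist as a covariate for the lists, were added after seeing the data. Counts of calls were also compared over the 35 ways to split the 8 libraries into 4 and 4. Figures were drawn with matplotlib.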

Results

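The transcriptome of the whole cerebellum was measured by polyA RNA sequencing at postnatal day 2 in 4 mutant pups and 4 control littermates. The mutants carried Math1-Cre with a floxed and a null allele of Sufu, which encodes a negative regulator of Hedgehog signalling that binds the Gli transcription factors. Counts in genes came to between 21479565 and 26638284 per library, and 18739 to 19456 genes had a count. The controls carried a floxed and a wild-type allele, per the series text, so all cells of the mutants lacked 1 Sufu allele and the cells with active Cre could lose the other. The comparison asks how this genotype alters gene expression in the newborn cerebellum, and it does not separate the null allele from the Cre deletion.

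Sufu was lower in every mutant library than in any control library. Its level was 53.8 ± 5.72 CPM (SD, n = 4) in controls and 35.7 ± 3.45 CPM (SD, n = 4) in mutants, a log2 fold change of -0.59 (SE 0.11). Sufu fell when adjusted over the list alone, that of Hedgehog pathway components other than target genes (edgeR adjusted p = 0.00477), and its adjusted p over all 15789 genes tested was 0.381. The log2 fold change was -0.58 among the libraries with title letter P and -0.63 among those with R. In the exon bin counts, Sufu has 13 bins on chromosome 19, plus strand, and all 13 fell in the mutants, adjusted over the Sufu bins (edgeR adjusted p at most 0.0194).

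The decrease was uneven along the gene. Bins 4 to 9 stood at 0.368 to 0.439 of the control level, bins 1 to 3 at 0.499 to 0.621 and bins 10 to 13 at 0.605 to 0.724. Bins 4 to 9 held 30.3 ± 1.97% (SD, n = 4) of the Sufu bin counts in controls and 21.5 ± 2.45% (SD, n = 4) in mutants. An exact two-sided permutation test gave p = 0.0286, the smallest value that 4 against 4 libraries allow, but this set of bins was chosen after the values were seen. The share planned beforehand, over the bins that fell, could not differ because every bin fell. By Simes' method over 13351 genes the use of Sufu bins did not pass (edgeR adjusted p = 1), while the gene-level test of the same bins called it (adjusted p = 0.0407).

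**Figure D1:**
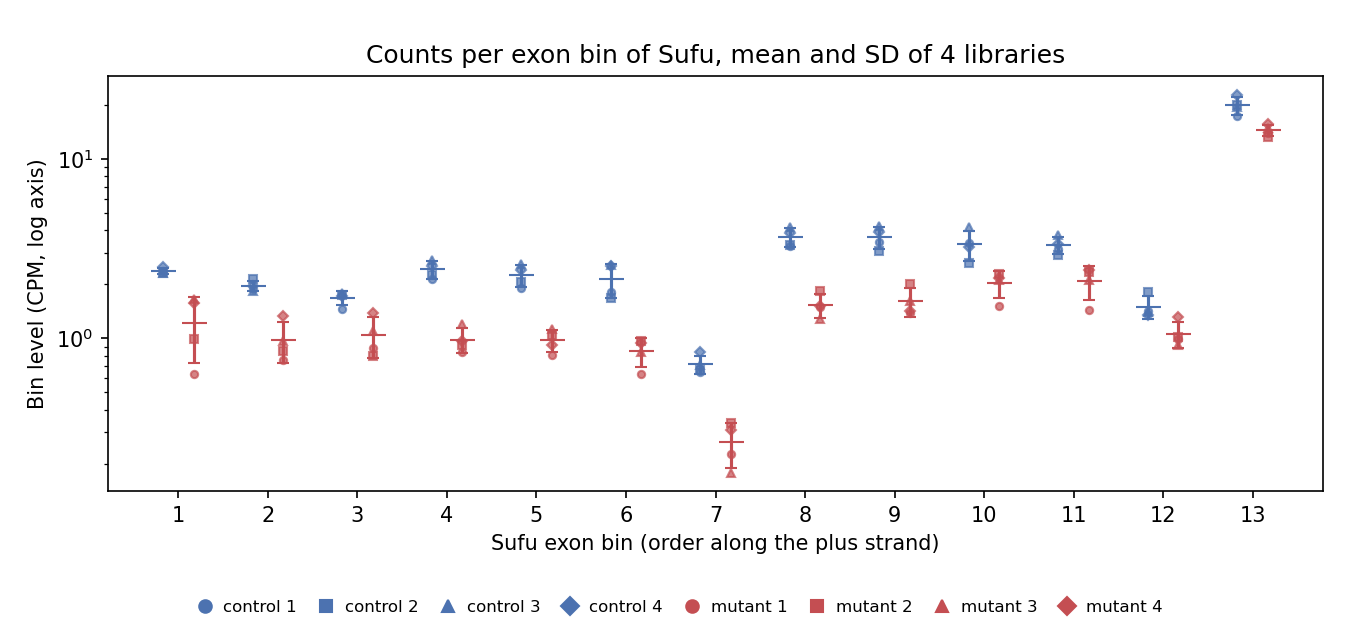
Level of each of the 13 Sufu exon bins, in CPM on a log axis, against the order of the bins; points are the 8 libraries, and horizontal marks with bars are the mean and SD of the 4 controls (blue) and the 4 mutants (red). The mutant means lie below the control means in every bin, by most in bins 4 to 9, at 0.368 to 0.439 of the control level.

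Fgf8, a secreted growth factor of the midbrain-hindbrain organizer, was 1.04 ± 0.26 CPM (SD, n = 4) in controls and 6.43 ± 3.44 CPM (SD, n = 4) in mutants, with a log2 fold change of 2.63 (SE 0.41). The mutant libraries held 2.41, 5.59, 7.03 and 10.7 CPM and the controls 0.70 to 1.33 CPM. Fgf8 rose when adjusted over the list alone, that of 16 tested FGF ligands and receptors (edgeR adjusted p = 8.87e-04), where it was the 1 member called; over all genes tested its adjusted p was 0.381. Fgf5, the next member by p, was 7.28 ± 2.63 CPM (SD, n = 4) in controls and 13.01 ± 3.23 CPM (SD, n = 4) in mutants. The Fgf8 log2 fold change was 1.97 within title letter P and 3.02 within R. Without mutant 1, the lowest of the mutants, Fgf8 passed over all genes tested (adjusted p = 0.0137), and its adjusted p ranged from 1.92e-07 with DESeq2 to 1.0 over the alternatives. The FGF ligand and receptor list as a whole did not pass (camera adjusted p = 0.615), with a mean log2 fold change of 0.16 and a median of -4.6e-04.

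All 14 genes of the FGF/ERK feedback and target list had higher means in mutants, and 8 of them rose, adjusted over the list alone: Dusp4, Dusp5, Dusp6, Etv1, Etv5, Spry1, Spry2 and Spry4. Over all genes tested, 0 passed. The Spry and Dusp genes encode inhibitors of the pathway, and Etv1 and Etv5 encode transcription factors it induces. Etv5 was 93.8 ± 13.5 CPM (SD, n = 4) in controls and 166 ± 53.5 CPM (SD, n = 4) in mutants, and Dusp6 was 34.2 ± 3.17 CPM (SD, n = 4) and 50.5 ± 13.8 CPM (SD, n = 4). The list passed with the preset correlation (camera adjusted p = 4.33e-06, median log2 fold change 0.30), with adjusted p = 0.439 with an estimated correlation. Its score was 0.13, 0.30, 0.35 and 0.615 in mutants 1 to 4, against -0.10 to 0.10 in controls. The median was 0.23 without mutant 4 and 0.21 with the Hox genes as a covariate, an alternative chosen after seeing the data. The midbrain-hindbrain organizer list did not pass (camera adjusted p = 0.540), though 2 of its 11 tested members, Fgf8 and Otx2, rose when adjusted over the list alone. Its median log2 fold change was -0.08, while its mean was 0.18 and the test's direction was up.

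Hedgehog target genes were higher as a group, but their members went both ways. Of the 14 tested, 11 had higher and 3 lower means, and 0 passed, either over all genes or adjusted over the list alone. The list's camera adjusted p was 0.0169 with the preset correlation (median log2 fold change 0.25), with adjusted p = 0.455 with an estimated correlation. Cdk6, a kinase of the cell cycle, had a log2 fold change of 0.54 (SE 0.17), Ccnd1 0.45 (SE 0.18), Mycn 0.45 (SE 0.25), Ccnd2 0.42 (SE 0.15) and Foxm1 0.41 (SE 0.16). Sfrp1 stood at 0.25, Ptch1 at 0.24, Bmi1 at 0.13, Hhip at 0.12, Rab34 at 0.04, Bcl2 at -0.02 and Igfbp3 at -0.28. Gli1, the transcription factor most often read as the pathway's output, stood at 45.5 ± 7.41 CPM (SD, n = 4) in controls and 33.0 ± 10.9 CPM (SD, n = 4) in mutants, a log2 fold change of -0.46 (SE 0.21). Among 22 other pathway components, Boc, Evc, Gli2 and Gli3 rose and Sufu fell, adjusted over the list alone. Gli2, chosen after its values were seen, was 47.1 ± 7.16 CPM (SD, n = 4) in controls and 76.9 ± 29.5 CPM (SD, n = 4) in mutants, and Gli3 was 23.6 ± 0.73 and 34.0 ± 6.78 CPM (SD, n = 4). That list's camera adjusted p was 0.0329 with the preset correlation and adjusted p = 0.439 with an estimated correlation. The call on components ended without control 1, control 2 or mutant 2 (adjusted p = 0.0944, 0.0986 and 0.0646), and with Hox genes or Xist as a covariate or without both mutants that held Y-linked counts (adjusted p = 0.126, 0.298 and 0.128). Under the same 3 settings, all chosen for the lists after seeing the data, the call on targets ended as well (adjusted p = 0.204, 0.164 and 0.114). The Hedgehog target score was -0.04, 0.11, 0.19 and 0.50 in mutants 1 to 4, and without mutant 4 the median log2 fold change of the targets was 0.14. The median of the components was 0.11, against 0.04 without mutant 2 and 0.16 without control 3.

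**Figure D2:**
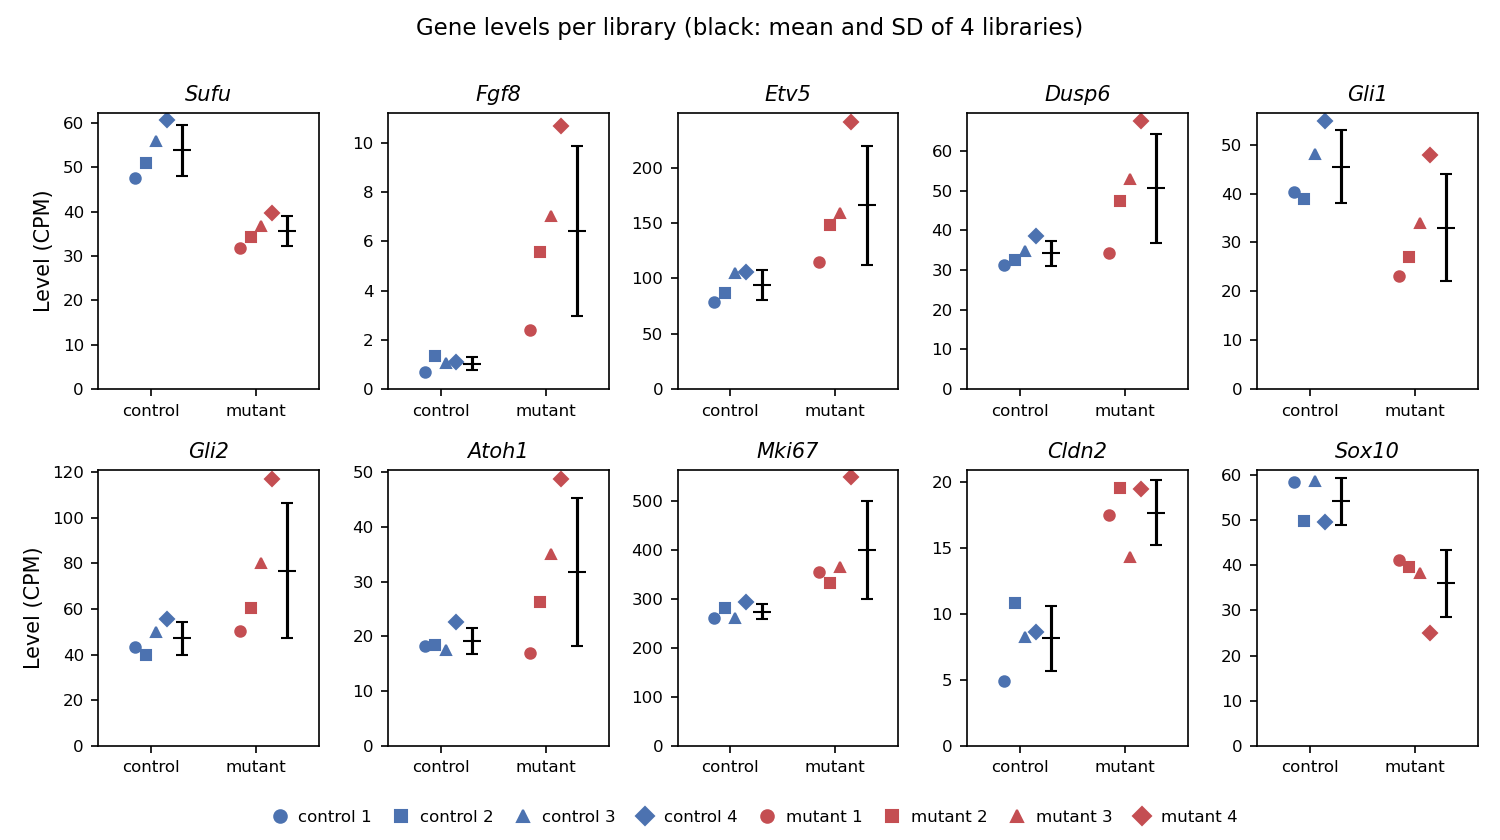
Levels of 10 genes in each of the 8 libraries, in CPM on axes that start at 0, with controls in blue, mutants in red and the mean and SD of each group of 4 in black. Fgf8 lies between 2.41 and 10.7 CPM in the mutants and between 0.70 and 1.33 CPM in the controls, while Gli1 is lower on average in mutants with overlapping ranges.

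Markers of granule cell precursors and of dividing cells were higher in mutants, unevenly across the 4 libraries. All 11 granule cell precursor markers had higher means, and Atoh1, Mfap4, Nhlh1, Pax6, Zic2, Zic4 and Zic5 rose, adjusted over the list alone (camera adjusted p = 3.15e-05 with the preset correlation, median log2 fold change 0.43, and adjusted p = 0.439 with an estimated correlation). Atoh1, the gene whose regulatory sequence drives the Cre, chosen after its values were seen, was 19.2 ± 2.36 CPM (SD, n = 4) in controls and 31.8 ± 13.5 CPM (SD, n = 4) in mutants. All 20 genes of G2/M and mitosis and all 20 of G1/S and DNA replication had higher means, but 0 of either list passed, adjusted over the list alone. The camera adjusted p was 6.86e-08 for G2/M (adjusted p = 0.439 with an estimated correlation) and 2.04e-05 for G1/S (adjusted p = 0.455 with an estimated correlation). Mki67 was 274 ± 15.96 CPM (SD, n = 4) in controls and 400 ± 99.6 CPM (SD, n = 4) in mutants. Log2 fold changes were 0.50 for Cenpf, 0.52 for Mcm6 and 0.53 for Cdc6. The granule precursor score was -0.02 in mutant 1, 0.27 in mutant 2, 0.51 in mutant 3 and 0.96 in mutant 4. Without mutant 4 the median log2 fold changes were 0.22 for granule precursor markers, 0.26 for G2/M genes and 0.19 for G1/S genes, and all 3 lists passed with the preset correlation, but not otherwise (adjusted p = 0.400, 0.400 and 0.585 with an estimated correlation). Differentiating granule neuron markers (camera adjusted p = 0.208, with Pde1c at 0.46 and Grin2c at 0.52) and cell cycle exit genes (adjusted p = 0.939, with Btg1 at 0.38 and Cdkn2d at -0.30) did not pass.

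Genes of the adjacent brainstem and midbrain were lower in mutants, most of all in mutant 4. Of 14 tested, 13 had lower means and Isl1, a gene of cranial motor neurons, fell when adjusted over the list alone, from 5.44 ± 1.47 CPM (SD, n = 4) to 2.06 ± 0.96 CPM (SD, n = 4). Chat, the acetylcholine-synthesizing enzyme, was 2.74 ± 0.26 CPM and 1.25 ± 0.99 CPM (SD, n = 4). The list had a camera adjusted p of 2.77e-05 with the preset correlation and adjusted p = 0.439 with an estimated correlation. The mean log2 score of the Hox genes, which mark the hindbrain behind the cerebellum, was 0.11 in mutant 1, -1.31 in mutant 2, -0.57 in mutant 3 and -4.27 in mutant 4, against -0.43 to 0.37 in controls. Hoxb3, chosen after its values were seen, stood at 1.08 CPM in mutant 4 and at 33.9 to 36.2 CPM in controls. With the Hox genes as a covariate, an alternative chosen after seeing the data, the brainstem list no longer passed (camera adjusted p = 0.390). Those Hox genes are themselves members of the brainstem list, so this loss was largely built in and says nothing of its cause. With the same covariate, median log2 fold changes were 0.17 for granule precursor markers, 0.19 for G2/M genes and 0.12 for G1/S genes. All 3 of these lists had a camera adjusted p under the threshold with the preset correlation. With an estimated correlation and this covariate they did not pass (adjusted p = 0.548, 0.548 and 0.685 with an estimated correlation). The brainstem call also ended with Xist as a covariate (adjusted p = 0.0605), and its median log2 fold change of -0.90 was -0.51 without mutant 4 and -1.37 without mutant 1.

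The choroid plexus score was higher in each of the 4 mutants, at 0.65 to 1.06, than in any control, at -0.44 to 0.44. Of the 10, 9 rose when adjusted over the list alone, among them Ttr, which encodes the abundant carrier transthyretin and was chosen after its values were seen, at 2406 ± 784 CPM (SD, n = 4) in controls and 4457 ± 1011 CPM (SD, n = 4) in mutants, and Cldn2 at 8.14 ± 2.45 and 17.7 ± 2.44 CPM (SD, n = 4). Otx2, which is also in the organizer list, was 25.6 ± 2.96 and 41.1 ± 6.24 CPM (SD, n = 4). The list had a camera adjusted p of 4.76e-08 with the preset correlation and adjusted p = 0.439 with an estimated correlation. Endothelial and pericyte markers were also higher as a list (camera adjusted p = 1.12e-04, with adjusted p = 0.439 with an estimated correlation), all 10 in the same direction, with Kdr at a log2 fold change of 0.46 and Pecam1 at 0.33. Meningeal markers did not pass (adjusted p = 0.950), with Crabp2 at -0.74 and Aldh1a2 at -0.57.

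Markers of the oligodendrocyte lineage were lower in mutants, and Cnp, Cspg4, Mag, Mbp, Olig1 and Sox10 fell, adjusted over the list alone. Sox10 was 54.2 ± 5.20 CPM (SD, n = 4) in controls and 36.0 ± 7.37 CPM (SD, n = 4) in mutants, and Cnp 168 ± 38.7 and 103 ± 22.7 CPM (SD, n = 4). The camera adjusted p was 3.87e-05 with the preset correlation and adjusted p = 0.439 with an estimated correlation. The oligodendrocyte score was -0.28 to -0.49 in mutants 1 to 3 and -1.30 in mutant 4, the library with the lowest Hox score (-4.27). The list's median log2 fold change was -0.53, and -0.34 with the Hox genes as a covariate. All 11 microglial markers had lower means (camera adjusted p = 5.60e-05, with adjusted p = 0.439 with an estimated correlation), with Aif1 at a log2 fold change of -0.73 and C1qa at -0.38, and 0 passed adjusted over the list alone. GABAergic interneuron markers were lower (camera adjusted p = 0.0311, with adjusted p = 0.441 with an estimated correlation), with Sst at -0.79 and Slc32a1 at -0.57. Their score was -0.12, -0.30 and -0.18 in mutants 1 to 3 and -0.83 in mutant 4, against -0.26 to 0.22 in controls. Their median log2 fold change was -0.22; it was -0.14 without mutant 4, -0.13 without control 3, -0.34 without control 2 or without mutant 1, and -0.06 with the Hox genes as a covariate. Purkinje cell markers were higher (camera adjusted p = 0.0169, with adjusted p = 0.455 with an estimated correlation), with Ppp1r17 at 0.68 and Rora at 0.32. Bergmann glia and astroglia markers did not pass (adjusted p = 0.694) and held members in both directions, with Gfap at -0.95 and Nes at 0.42. Markers of the cerebellar nuclei and unipolar brush cells did not pass either (adjusted p = 0.633), with Eomes at 0.43 and Lhx2 at -1.02. Lhx2 turned with title letter, at 0.25 within P and -2.37 within R (interaction adjusted p = 0.0320), and leaving out 1 library gave -1.46 to -0.60. The Purkinje call ended without control 1, control 2, mutant 1 or mutant 4 (adjusted p = 0.0944, 0.183, 0.0727 and 0.0557), and the GABAergic call ended without control 3, control 4 or mutant 2 (adjusted p = 0.0646, 0.198 and 0.0991) and with the title letter as a block (adjusted p = 0.0604). It ended too with Hox genes or Xist as a covariate and without both mutants that held Y-linked counts (adjusted p = 0.258, 0.245 and 0.115).

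**Figure D3:**
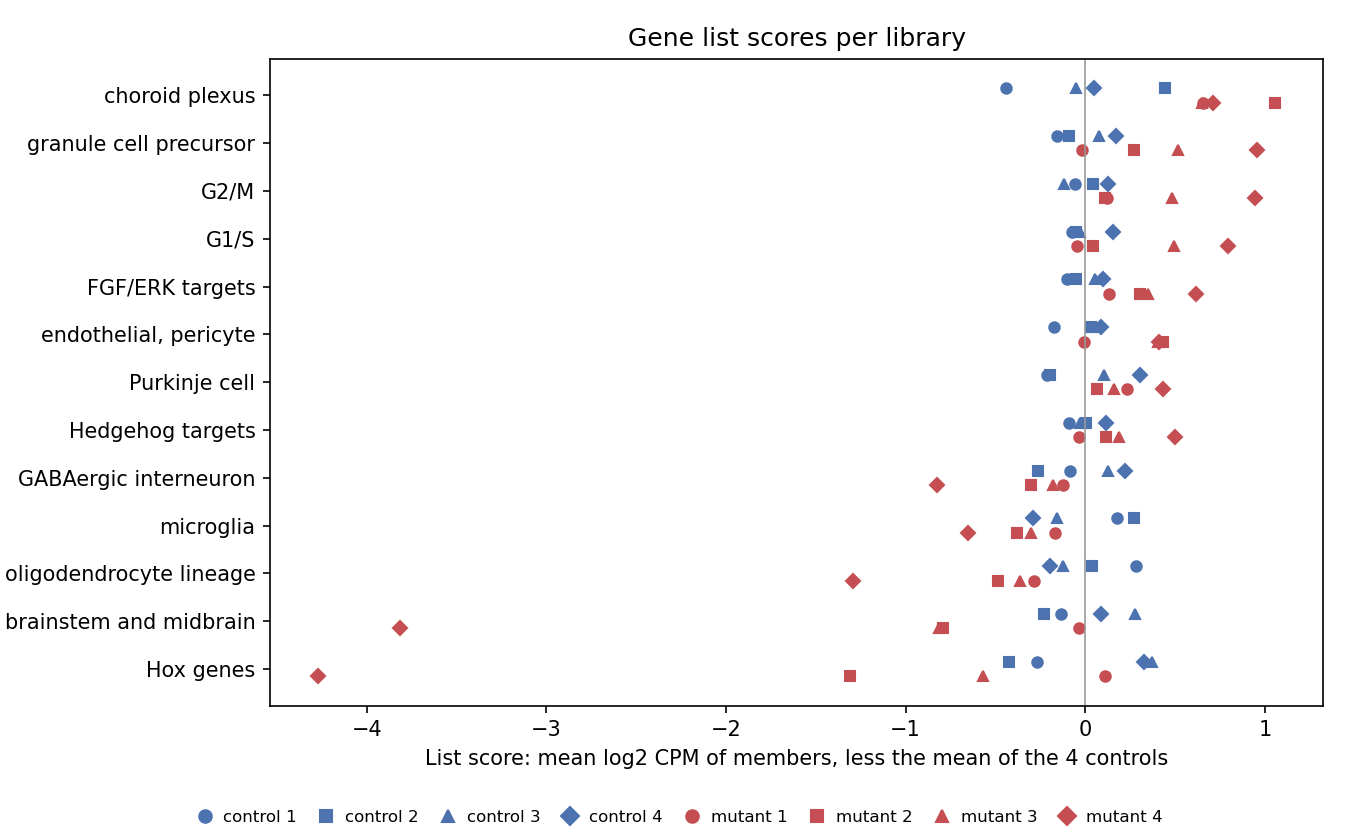
Scores of 13 gene lists in each library, as the mean log2 CPM of the members less the mean of the 4 controls, with controls in blue and mutants in red. Hox genes reach -4.27 in mutant 4, while the granule precursor list reaches 0.96 in the same library and the choroid plexus list is above every control in all 4 mutants.

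Cholesterol synthesis genes were lower (camera adjusted p = 0.00148, with adjusted p = 0.439 with an estimated correlation), 15 of 16 in the same direction, with Fdps at a log2 fold change of -0.36 and Mvd at -0.25. Glycolysis genes were lower (camera adjusted p = 0.00354, with adjusted p = 0.439 with an estimated correlation), with Aldoc at -0.67 and Aldoa at -0.32. WNT target genes were higher (camera adjusted p = 0.0436, with adjusted p = 0.439 with an estimated correlation), with Nkd1 at 0.45 and Lef1 at 0.43. Lists that did not pass were BMP targets (adjusted p = 0.655, with Msx1 at 0.59 and Msx2 at 0.54), Notch targets (adjusted p = 0.939, with Hey1 at 0.57 and Hes1 at 0.55), p53 targets (adjusted p = 0.950, with Eda2r at 0.66 and Phlda3 at -0.61), immediate early genes (adjusted p = 0.0656, with Arc at -0.40 and Fos at -0.33) and the neighbours of Sufu on its chromosome (adjusted p = 0.422, with Psd at -0.46 and Sfxn2 at 0.39). Medians and test directions had opposite signs for p53 targets (median -0.01, up), and the median and mean did for Notch targets (-0.06 and 0.06). The glycolysis call ended without mutant 1 (adjusted p = 0.0607), and the WNT call without control 1, control 2, mutant 2 or mutant 4 (adjusted p = 0.101, 0.117, 0.0727 and 0.102), with Hox genes or Xist as a covariate, and without both mutants that held Y-linked counts (adjusted p = 0.204, 0.325 and 0.297). The immediate early list passed with the preset correlation without control 1, control 2, mutant 3 or mutant 4 (adjusted p = 0.0481, 0.0427, 0.0326 and 0.0435) and with Hox genes or Xist as a covariate (adjusted p = 0.0438 and 0.0388). In none of these 6 settings did it pass with an estimated correlation (lowest adjusted p = 0.400 with an estimated correlation). The red blood cell list had 1 tested member, Alas2, at -0.13, and the sex chromosome list had 1, Xist; neither list could be tested.

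Over all 15789 genes tested, 0 passed the edgeR quasi-likelihood test at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1095 genes higher and 900 lower. Without control 1 these numbers were 588 and 568, without control 3 they were 651 and 484, without mutant 1 they were 1513 and 1673, and without mutant 4 they were 478 and 563. DESeq2 called 52 genes, 40 higher and 12 lower, of which 3 were Y-linked, and limma-voom called 0. Of the DESeq2 calls, 48 were among the 100 genes with the smallest p in edgeR. They included Fgf8 and Sufu, and, chosen here after their values were seen, Plagl1, an imprinted gene for a zinc finger protein (log2 fold change 0.69 by edgeR, 101.8 ± 11.1 CPM in controls and 164 ± 12.1 CPM in mutants, SD, n = 4), Chrnb4, a nicotinic receptor subunit (1.25), Insm2 (1.49), 2410127L17Rik (1.19) and the neurofilament gene Nefl (-0.75). Of the 28 lists, 16 passed camera with the preset correlation, 10 higher and 6 lower, and 0 passed with an estimated correlation or with fry. With the title letter as a block 15 lists passed and 0 genes, with 1561 higher and 1418 lower at an unadjusted p under 0.05. Within letter P alone 5 genes passed, Gh, Gm8801, Prph, Rpl22l1 and Rpl39, all named here after their values were seen.

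The mutant libraries were not alike. The first principal component held 60.5% of the variance among the 500 most variable genes and placed mutant 4 at 39.2, apart from mutants 3, 2 and 1 at 7.74, 1.36 and -7.25 and from the controls at -12.9 to -7.58. All mutants lay above all controls on it (exact two-sided permutation p = 0.0286, the smallest possible). Xist, which is expressed from the inactive X chromosome of females, was at 1449 to 2197 CPM in all 4 controls and in mutants 1 and 3, and at 1.76 and 0.82 CPM in mutants 2 and 4, where Kdm5d, on the Y chromosome and chosen after its values were seen, stood at 44.6 and 50.5 CPM. Kdm5d had no counts in the other libraries, and the labels used here give no sex. With Xist as a covariate, 177 genes were higher and 113 lower at an unadjusted p under 0.05, with 0 past the adjusted threshold in edgeR. Without both of the libraries that held Y-linked counts, an alternative chosen after seeing the data, these numbers were 267, 357 and 0.

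Exon bin use was compared to ask whether transcript structure differed beyond Sufu. One gene passed, Lars2, the mitochondrial leucyl-tRNA synthetase on chromosome 9 (edgeR diffSpliceDGE, Simes adjusted p = 1.76e-06), out of 13351 tested, with 31 genes at an unadjusted p under 0.05. The last Lars2 bin stood at 2276 CPM in mutant 2 and 396 CPM in mutant 1, against 118 to 226 CPM in the other libraries. All other Lars2 bins together stood at 24.0 to 29.2 CPM over the 8 libraries, so the call rested on the level of the last bin. Rn45s, the ribosomal RNA precursor, chosen after its values were seen, was at 16230 CPM in mutant 2, 1917 CPM in mutant 1 and 699 to 1185 CPM elsewhere. Without mutant 2, Lars2 was not called and Fau was; without control 2, Trpm3 was called as well, and without control 3, Nf2, making 2 genes each time. Fau, Gnas, Dpp6 and Mfsd4, the next genes by p, did not pass (adjusted p = 0.254, 1, 1 and 1), and the gene-level test called 3 genes, Lars2, Araf and Sufu. With limma's diffSplice 1 gene passed, Adam9, and Lars2 did not.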

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

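The tests of Fgf8, of the granule precursor and cell cycle lists and of the choroid plexus list in this part were chosen only after the results were seen. In 15 of 258 groups of 4 libraries, 1 library stood apart from the other 3 by Dixon's gap-to-range ratio, and chance gives about 1 in 20. Mutant 4 stood apart from the other mutants for Gli3 (ratio 0.866, higher), Sst (0.832, lower), Sox10 (0.862, lower), Crabp2 (0.939, lower), Hoxd3 (0.831, lower), Nefl (0.92, lower) and its total of bin counts (0.872, higher). Mutant 2 stood apart for the choroid plexus score (0.855, higher) and the Rn45s percent of counts (0.938, higher), and mutant 1 for the endothelial and pericyte score (0.94, lower). Among controls, control 1 stood apart for Lef1 (0.935), Sfxn2 (0.868) and Ttr (0.859), all lower, control 2 for Bcl2 (0.84, higher) and control 4 for the Notch target score (0.879, higher). The genotype effect on Lhx2 differed between title letters by -2.599 log2 units (edgeR interaction term, adjusted p = 0.0320). It was 1 of 505 genes that passed this test, against 0 in the main test of genotype, which assumes the same effect in both letters. With 2 control and 2 mutant libraries per letter, the interaction cannot be told apart from single pups that stood apart. Reads outside annotated genes made up 17.66% in mutant 2 and 17.26% in mutant 1, against 12.25 to 15.07% in controls, and 14.2 to 17.7% over title letter P against 12.2 to 13.7% over R.

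Higher Fgf8 in the mutants was weighed against a smaller share of brainstem in the dissected tissue and against the male pups among the mutants. The Fgf8 log2 ratio to the control mean exceeded the granule precursor score of the same library by 2.008 on average (SD 0.5303, n = 4), and with the Hox genes as a covariate its log2 fold change was 2.016 (SE 0.347). A smaller share of brainstem would raise both alike, so these values argue against it as the whole cause. Without the mutants that held Y-linked counts the log2 fold change of Fgf8 was 2.175 (SE 0.404), which argues against pup sex as the whole cause. An effect of the Sufu genotype stays open as a hypothesis, found and tested on the same libraries.

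Higher granule precursor and cell cycle lists cannot be told apart from a smaller share of adjacent brainstem, which would raise all cerebellar markers alike. With the Hox genes as a covariate, the lists kept at most 41.28% of their median log2 fold change (40.78% for granule precursor markers, 30.33% for G1/S and 41.28% for G2/M). This loss does not single out the brainstem share, because the Hox score was by far the lowest in mutant 4 (-4.27). Leaving out mutant 4 gave medians of 0.22, 0.19 and 0.26 in the same order. Xist as a covariate, which is no brainstem marker, gave 0.23, 0.24 and 0.30. Of 9 comparisons with Purkinje, Bergmann and astroglia, and differentiating granule markers, 2 lay beyond 1 SD. Both were with Bergmann and astroglia, at 0.42 (SD 0.38) for granule precursors and 0.40 (SD 0.33) for G2/M, but astroglia are also part of the brainstem. With Purkinje markers granule precursors differed by 0.21 (SD 0.3315). The SD is the spread of the 4 mutants, not the error of their mean, so a difference within it does not show that lists rose alike. Granule precursor scores were -0.02, 0.27, 0.51 and 0.96 in mutants 1 to 4. Those of differentiating granule markers were 0.06, 0.08, 0.03 and 0.16. Pup sex cannot be told apart either with 2 pups: in the mutants without Y-linked counts the mean scores were 0.2241 (SD 0.3783) for G1/S and 0.2484 (SD 0.3749) for granule precursors, within the SD, and 0.3019 (SD 0.2578) for G2/M, beyond it, and without the other mutants all 3 lists passed camera with the preset correlation (medians 0.26, 0.24 and 0.31) but not otherwise (adjusted p = 0.536, 0.536 and 0.510 with an estimated correlation). An effect of genotype stays open, as it was not tested apart from the brainstem share; with the covariate the lists passed camera with the preset correlation but not otherwise (adjusted p = 0.548, 0.685 and 0.548 with an estimated correlation for granule precursor, G1/S and G2/M).

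Higher choroid plexus markers may reflect more choroid plexus tissue in the mutant samples. Of the 9 markers compared, 1 lay over 2 SE from their median log2 fold change of 0.8476, Prlr at -0.20. The other 8 lay within it, as a rise of 1 tissue in 1 ratio would need, and Prlr is an exception to it. With SEs of 0.20 to 0.26 for those 8, the 2 SE band also admits markers that rose by different ratios. The test therefore gives little support. Whether more plexus was taken at dissection or more had formed was not told apart by this test. The levels of Ttr and Enpp2, the most abundant of these markers, were 4457 and 471 CPM in mutants and 2406 and 284 CPM in controls.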

How the results depend on the processing

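The settings with Hox or choroid plexus genes as a covariate, Xist as a covariate for the lists, and those without both mutants that held Y-linked counts were chosen only after the results were seen. Sufu stayed lower and Fgf8 higher under every alternative run, at log2 fold changes of -0.66 to -0.53 for Sufu and 1.97 to 3.02 for Fgf8. For the changes listed next, the cause was not tested, except that single letters and left-out libraries hold fewer samples.

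DESeq2 called 40 genes higher and 12 lower. Title letter P alone gave 1 higher and 4 lower, and letter R alone gave 1 lower, with 2218 higher and 2541 lower at an unadjusted p under 0.05. At that level there were 1418 lower with the letter as a block, 177 higher and 113 lower with Xist as a covariate, 237 and 179 with Hox genes, 106 and 181 with choroid plexus genes, and 267 and 357 without both mutants that held Y-linked counts. Leaving out 1 library at a time gave 0 to 1 genes higher and 0 to 0 lower past the adjusted threshold in edgeR, 478 to 1513 higher and 484 to 1673 lower at an unadjusted p under 0.05, 13 to 17 lists, and 1 to 2 genes with changed exon use. With an estimated correlation 0 lists passed, and with fry 0 lists, against 16 with the preset; 12 passed with Hox genes as a covariate, 12 with Xist and 12 without both mutants that held Y-linked counts. The gene-level test of bins called 3 genes. Without both mutants that held Y-linked counts, diffSpliceDGE called 0.

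Of the values of named genes under the alternatives, 2071 kept their direction and side of the threshold, 19 newly passed and 24 turned. Of those of lists, 408 kept both, 62 no longer passed and 6 newly passed. Over all genes 0 passed the main edgeR test, so named genes that kept their side of the threshold stayed short of it. For the same reason, none of the genes that turned could have passed before. Ttr and Hoxd3 are themselves part of the covariate under which they turned. With letter P alone log2 fold changes were 0.05899 for Bcl2, -0.1332 for Bmi1, -0.1304 for Rab34, 0.2508 for Lhx2, 0.01006 for Alas2, -0.1084 for Ptf1a and -0.0182 for Etv4. With Hox genes as a covariate they were 0.02329 for Bcl2, -0.033 for Rab34, 0.002662 for Alas2, -0.04895 for Ptf1a and 0.002167 for Hoxd3. With choroid plexus genes as a covariate they were -0.008539 for Lef1, -0.0606 for Ttr, -0.1223 for Rn45s and -0.1914 for Lars2, and without both mutants that held Y-linked counts 0.1592 for Xist. Leaving out 1 library at a time gave -0.1263 to 0.08026 for Bcl2, -0.37 to 0.05043 for Alas2, -0.0327 to 0.1038 for Rab34 and -0.04827 to 0.4057 for Ptf1a.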

Other observations

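The genes described in the next paragraph and the comparison with splits balanced for title letter were chosen only after the results were seen, while the comparison with all splits of the libraries was set beforehand.

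Several genes outside the fixed lists differed in mean between genotypes without passing the edgeR test over all genes. Chrna3, a nicotinic receptor subunit gene, was 42.2 ± 4.63 CPM (SD, n = 4) in controls and 66.1 ± 14.9 CPM (SD, n = 4) in mutants, higher in 4 of 4 mutants than in any control. Ntf3, a neurotrophin gene, was 5.86 ± 1.11 and 11.9 ± 4.04 CPM (SD, n = 4). Prph, which encodes peripherin, a filament of neurons that project outside the brain, was 54.7 ± 7.64 and 12.5 ± 9.10 CPM (SD, n = 4), and Calca was 6.10 ± 1.89 and 2.52 ± 1.13 CPM (SD, n = 4), with overlapping ranges. In mutant 4, the library with the lowest Hox score, Prph stood at 1.41 CPM. It was also lower in mutant 1, whose Hox score was 0.11, at 21.7 CPM against 45.4 to 61.5 CPM in controls. Car12 was 19.7 ± 5.86 and 40.9 ± 7.51 CPM (SD, n = 4), and its log2 fold change of 1.06 was 0.19 (SE 0.18) with choroid plexus genes as a covariate, so it moved with those markers. Bmp5 was 7.02 ± 1.46 and 14.1 ± 3.62 CPM (SD, n = 4).

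Over the 35 splits of the 8 libraries into 4 and 4, chance was not excluded for the count at an unadjusted p, the lists or exon use. The real split gave 0 genes past the adjusted threshold in edgeR, with 1995 at an unadjusted p under 0.05, 52 by DESeq2 and 0 by limma-voom. All 35 splits must give as many as 0, so that comparison says nothing; the highest other gave 4. At an unadjusted p under 0.05, 5 of 35 splits gave 1995 genes or more, and the highest other, 3468, was the split by title letter. Of the 18 splits with 2 libraries of each letter in both groups, the real one gave the most, with 1571 the highest other, but 18 splits cannot give a share under 0.05. For the gene lists, 3 of 35 splits gave 16, with 16 the highest other, and 2 of the 18 balanced splits did. For exon use, 30 of 35 splits gave 1 gene or more, and the highest other, again the title letter, gave 68, which points to a structure of the samples. With the title letter as a block, 1 gene was called for exon use, 15 lists passed and 0 genes passed in edgeR, with 1561 higher and 1418 lower at an unadjusted p under 0.05.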
